A study of Mus musculus with 6 samples.

How the data were processed

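Haematopoietic stem cells from mouse fetal liver were compared between a wild type group (WT) and a group with a knockout of Uqcrfs1 (KO), the gene of the Rieske iron-sulfur protein (RISP) of respiratory complex III. Each group had 3 libraries of C57BL/6 cells. Per the labels' protocols, libraries were made from nanogram amounts of total RNA with a strand-marking kit for very low input (SMARTer Stranded Total RNA-seq, Pico input) and sequenced on an Illumina NextSeq500. The labels do not say whether the 3 libraries of a group came from separate embryos or litters, so p-values measure only the spread between these libraries, which may be partly technical.

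The authors deposited 1 table of read counts per gene symbol and 1 table of RPKM values (reads scaled by gene length and library size), each with 1 column per library and 23951 genes. The deposited counts were whole numbers with no normalization. Per the submitters' processing notes, reads were handled with TopHat and Cufflinks on the mm9 build of the mouse genome. Software versions, the read counter, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical genes such as histone, ribosomal protein and lysozyme genes carry that uncertainty. The deposited RPKM values did not follow from the deposited counts by a single length per gene, and 180 genes with 0 counts in every library had a mean RPKM of at least 0.5. Total counts were 10191354, 10943143 and 13189329 in WT replicates 1 to 3 and 14313927, 14590844 and 12020128 in KO replicates 1 to 3. Reads from PCR without molecular identifiers are not independent molecules, so limits set by a count of 0 cover counting error only.

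Differences were tested on the counts with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the group, robust quasi-likelihood F test, group as the only term). P-values were adjusted by Benjamini-Hochberg over the 12204 genes kept, with a threshold of 0.05. Counts scaled to a common library size (CPM) were scaled by the TMM library sizes, and errors of CPM are standard deviations over 3 libraries. The standard error (SE) of a log2 fold change was the size of the fold change divided by the square root of its F statistic. The SE of a list's median came from 2000 resamples of the list's genes. Such genes are not independent, so this SE leaves out the spread between libraries. For genes with 0 counts in every library of a group, a lower bound of the fold was computed from 3 counts over that group. Replicate pairs within a group were checked with a chi-square statistic of their counts. It lay between 21.7 and 43.1 per degree of freedom, so no pair agreed within counting noise. PCR can also spread technical repeats beyond counting noise, so this does not show that libraries are separate biological samples. Counts of Xist and of 4 Y-linked genes tell most libraries apart. They were 13480 and 0 in KO replicate 1, 0 and 2358 in KO replicate 2, and 16004 and 604 in KO replicate 3. These libraries were thus not repeats of 1 RNA sample. WT replicate 1 had 13 Y-linked counts, against 836 and 1022 in WT replicates 2 and 3, which these counts do not clearly separate. Each library was counted as 1 replicate, as the labels name it a sample of its own.

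There were 45 gene lists, fixed before the data were examined: respiratory complexes I to V, the mitochondrial genome, mitochondrial ribosome, TCA cycle, glycolysis, pentose phosphate pathway, integrated stress response (ATF4 targets), mitochondrial chaperones and proteases, endoplasmic reticulum stress, NRF2 and antioxidant genes, HIF targets, p53 targets, BCL2 family, S phase, G2/M, quiescence and cell cycle inhibitors, stem cell programme, fetal stem cell genes, erythroid, megakaryocyte, granulocyte, macrophage and monocyte, mast cell with basophil and eosinophil, lymphoid, hepatoblast, endothelial, stromal, interferon response, NF-kB, immediate early genes, cytosolic ribosome, chromatin enzymes, one-carbon and serine metabolism, nucleotide and aspartate metabolism, fatty acid oxidation, cholesterol synthesis, haem and iron-sulfur clusters, mitochondrial biogenesis and dynamics, autophagy and lysosome, replication-dependent histones, and sex-linked genes. The last list only described the libraries. No gene of the mitochondrial genome was among the genes tested, and that list was not analysed here. The other 43 lists, each with at least 5 tested members and without Uqcrfs1 itself, were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run beside it. In the 4 lists that held 1 gene at 0 in a whole group, the median was the same with that gene at its bound.

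The rule for named genes was also fixed before the data were examined. It took Uqcrfs1, and the 15 largest rises and 15 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes and small RNA genes. It also took the members with the smallest p of each list, the 2 most abundant members of each list of another cell type, and Xist with 4 Y-linked genes. Some genes that the rule takes are not reported here. Genes outside it are said to have been chosen after their values were seen. Gene positions, transcript lengths and GC contents came from a GRCm38 annotation, matched by symbol. Since the authors' files used mm9, no coordinates are given, and positions served only to find neighbours. A length and GC value was found for 99.4% of the tested genes.

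The alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, other filters on low counts and non-robust shrinkage. They also included the replicate number as a block, an adjusted p of 0.1 and a minimum log2 fold change of 1. Further ones removed mitochondrial, haemoglobin and short non-coding RNA genes together with the ribosomal RNA precursor Rn45s, or the 50 most abundant genes. Each library was also left out in turn, and limma was run on log2(RPKM + pseudocount) with pseudocounts of 1, 0.1 and 0.5. Offsets for transcript length and GC content (smooth terms per library, mgcv 1.9.3), the offsets together with the block, a covariate for the Y-linked level, and the one-carbon list without its stress response members were chosen after seeing the data.

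The scripts were tested on simulated counts with the means, dispersions and depths of these libraries. In the simulated comparison of KO and WT over 11983 genes, edgeR recovered 34.7% of genes changed by a log2 fold of 1 and 81.4% of those changed by 2, and 3.42% of its calls were unchanged genes. With no change simulated, 2 of 11948 genes and 0 lists were called, in genes drawn independently of each other.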

Results

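Gene expression was measured by total RNA sequencing in haematopoietic stem cells (HSCs) from mouse fetal liver, in 3 wild type (WT) and 3 Uqcrfs1 knockout (KO) libraries. Uqcrfs1 encodes the Rieske iron-sulfur protein, or RISP, a catalytic subunit of respiratory complex III that passes electrons from ubiquinol towards cytochrome c. Total counts per library were 10191354 to 13189329 in WT and 12020128 to 14590844 in KO. Between 13083 and 13551 genes were detected per library. The single comparison of the design, KO against WT, addresses which transcripts change in fetal HSCs that lack this subunit.

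Uqcrfs1 itself was read first in every library. It had 771, 1320 and 791 counts in WT replicates 1 to 3 and 60, 51 and 39 counts in KO replicates 1 to 3. Its level was 87.1 ± 32.1 CPM in WT and 3.60 ± 0.650 CPM in KO (SD, n = 3 each), a fall by 4.59 on the log2 scale with an SE of 0.29 (edgeR, Benjamini-Hochberg adjusted p = 4.11e-09). All 6 libraries matched their labels by this gene, and reads remained in every KO library. Which part of the gene was deleted is not given in the sources used here.

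In KO, 29 of 36 genes of the integrated stress response list were higher, with Atf4 at 353 ± 14.8 CPM against 91.7 ± 9.75 CPM in WT (SD, n = 3 each). Of cholesterol synthesis genes 12 of 22 were lower, with Idi1 at 16.7 ± 4.29 against 61.3 ± 13.7 CPM, and of erythroid genes 12 of 25, with Alas2 at 6.84 ± 3.32 against 52.0 ± 17.6 CPM. The camera calls of these 2 lists were lost with an estimated correlation (adjusted p = 0.234 and adjusted p = 0.156). Across the transcriptome, 1391 of 12204 genes tested (11.4%) differed between KO and WT, 782 higher and 609 lower, at an adjusted p under 0.05 (edgeR). Of these, 217 rose and 248 fell by a log2 fold of at least 1. The 3 KO libraries lay apart from the 3 WT libraries on the first principal component, which held 38.5% of the variance. The count depended on single libraries. It was 712 without KO replicate 2 and 833 without KO replicate 3, and the lower genes numbered 383 without WT replicate 1. Of the 145 named genes past the threshold, 85 kept their call whichever library was left out, which says nothing of other settings. With limma on log2(RPKM + 1), 70 of the 144 tested lost it, among those named below Ptprv, Prss34, Pycr1, Pfkl, Fth1, Slc25a37, Pcna, Vwf, Mycn, Cd34, Kit, Car2, Mmrn2, Msr1, Pcdh17, Trf, Mpo, Selp, Dnmt3a, Dnmt1, Zmat3 and Mdh1. With a pseudocount of 0.1 Nupr1 and Ankrd63 also lost it, and with 0.5 and no filter 103 of 145 did. Of 43 gene lists tested with camera, 8 passed the threshold upwards and 17 downwards. Each split of the libraries other than the real one gave 9 to 14 lists past it with 0 genes called. Those splits keep WT and KO libraries on both sides in unequal number, so these counts are no rate of false calls. In the real comparison, 1 list passed with an estimated correlation. For genes outside those 85, the highest adjusted p over the 6 fits that left out 1 library is given where they are named.

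Among the largest rises were genes of amino acid supply and of the stress response driven by ATF4, the transcription factor at the centre of the integrated stress response. Atf4 rose by 1.95 on the log2 scale with an SE of 0.12 (edgeR, adjusted p = 4.11e-09). Its target Asns, the asparagine synthetase gene, rose from 47.5 ± 3.02 to 192 ± 6.86 CPM. Trib3, a pseudokinase gene and stress target, rose by 3.21 on the log2 scale, and Atf5 by 3.71. Of the 36 measured genes of the integrated stress response list, 29 rose and 0 fell over all genes tested, and 32 rose adjusted over the list alone. The list's median log2 fold change was 1.41 (camera, adjusted p = 3.93e-68). It was the only list whose call held with an estimated correlation after adjustment, with an adjusted p of 0.00456.

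Several of these genes were close to silent in WT. Aldh1l2, a mitochondrial folate enzyme, had 0, 5 and 0 counts in WT and 411, 681 and 615 in KO, a log2 fold change of 8.01 with an SE of 0.65. Slc7a3, a transporter of cationic amino acids, had 5, 0 and 0 counts in WT and 248, 363 and 192 in KO. Nupr1, a stress-induced chromatin protein gene, rose by 5.91 (SE 0.60), and Cth, which makes cysteine from cystathionine, by 5.89 (SE 1.00). Slc7a11, the cystine transporter gene, reached 28.9 ± 0.352 CPM in KO from 1.94 ± 0.779 CPM. Bcat1, a branched-chain aminotransferase gene, rose by 3.66, and Stc2, which encodes a secreted glycoprotein, by 3.42. Chac1, a glutathione-degrading enzyme gene, rose by 5.26 but had an adjusted p of up to 0.129 when a KO library was left out, 0.0675 with DESeq2 and 0.117 with the Y-linked level as a covariate. Pycr1, of proline synthesis, rose by 3.24, with a highest adjusted p of 0.0503 without KO replicate 3. The large rises also included Ptprv at 4.89, Ankrd63 at 2.93 and Prss34, a mast cell and basophil protease gene, at 4.45, with a highest adjusted p of 0.158 and a value of 3.42 without KO replicate 3. With limma-voom Ptprv, Prss34 and Pycr1 did not pass (adjusted p = 0.0620, 0.195 and 0.0508). Without the only WT library with counts, WT replicate 2 for Aldh1l2 and Chac1 and WT replicate 1 for Slc7a3 and Cth, the fitted log2 fold changes were 12.05, 11.19, 10.96 and 10.82, which depend on the prior count and are no bounds. Without WT replicate 3 these 4 values were 7.36, 4.63, 6.23 and 5.26, and Nupr1, Ptprv and Stc2 stood at 6.68, 6.07 and 4.12.

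**Figure D1:**
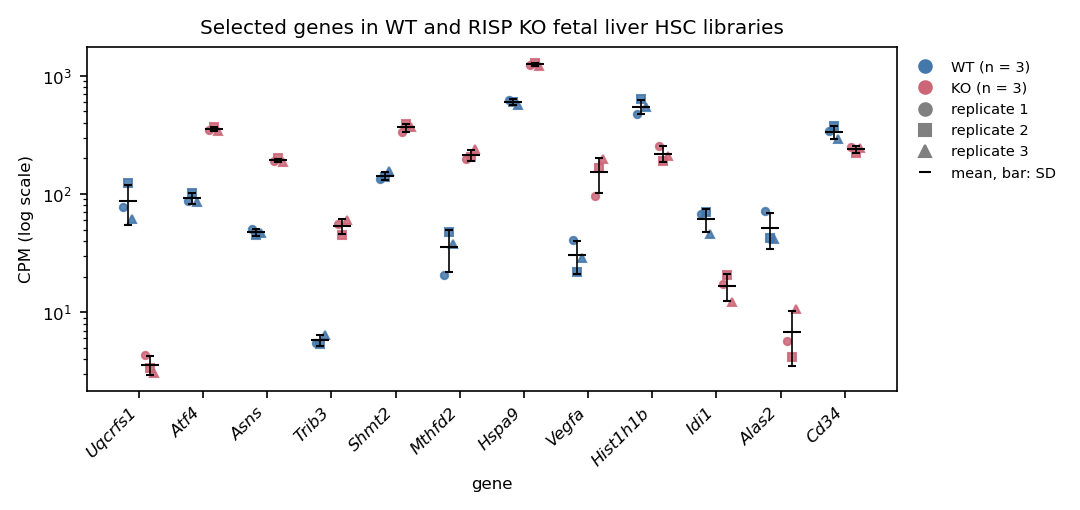
CPM on a log axis for 12 genes in the WT and KO libraries, with 1 symbol per library, horizontal marks at the means and bars for SDs over 3 libraries. Uqcrfs1 fell from a mean of 87.1 to 3.60 CPM and Atf4 rose from 91.7 to 353 CPM, with no overlap between the groups.

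The serine and one-carbon list passed upwards, and most of its higher genes are also in the stress response list. Shmt2, the mitochondrial serine hydroxymethyltransferase, went from 143 ± 11.5 to 366 ± 28.4 CPM, and Mthfd2, the mitochondrial methylene-tetrahydrofolate dehydrogenase, rose by 2.58 on the log2 scale (SE 0.25). Psat1, of serine synthesis, rose by 0.97 (SE 0.13). Of the 16 genes of the list, 7 rose and 0 fell over all genes tested, and 8 rose adjusted over the list alone (median 0.56, camera adjusted p = 6.59e-11). The call did not hold with an estimated correlation (adjusted p = 0.0738). The list shares 6 genes with the stress response list, and its other 10 genes had a camera p of 0.128, with 2 of them higher.

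The lists of mitochondrial chaperones and proteases, glycolysis and HIF targets passed upwards with a minority of members called. Hspa9, the mitochondrial Hsp70 gene, went from 597 ± 33.0 to 1250 ± 38.1 CPM (log2 fold change 1.07, SE 0.09), and Trap1, a mitochondrial Hsp90, rose by 0.67. In the list of mitochondrial chaperones and proteases, 4 of 16 genes rose and 0 fell, with 5 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.00838, and adjusted p = 0.266 with an estimated correlation). In glycolysis, 7 of 26 genes rose and 0 fell, and adjusted over the list alone 7 rose and 1 fell (median 0.30, camera adjusted p = 0.00134, and adjusted p = 0.259 with an estimated correlation). The glycolytic genes with the smallest p were Pfkp at a log2 fold change of 0.90, Hk2 at 0.73, Slc2a3 at 0.68 and Pfkl at 0.58, which encode phosphofructokinases, a hexokinase and a glucose transporter. The count of higher genes was 4 for glycolysis without WT replicate 1, KO replicate 1 or KO replicate 2, and 2 for chaperones and proteases without WT replicate 1 or KO replicate 2. Among HIF targets, 3 of 21 rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone (median 0.41, camera adjusted p = 0.00237, and adjusted p = 0.192 with an estimated correlation). The angiogenic growth factor gene Vegfa rose by 2.32 (SE 0.29), while Bnip3l, a mitophagy receptor gene, fell by 0.66.

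**Figure D2:**
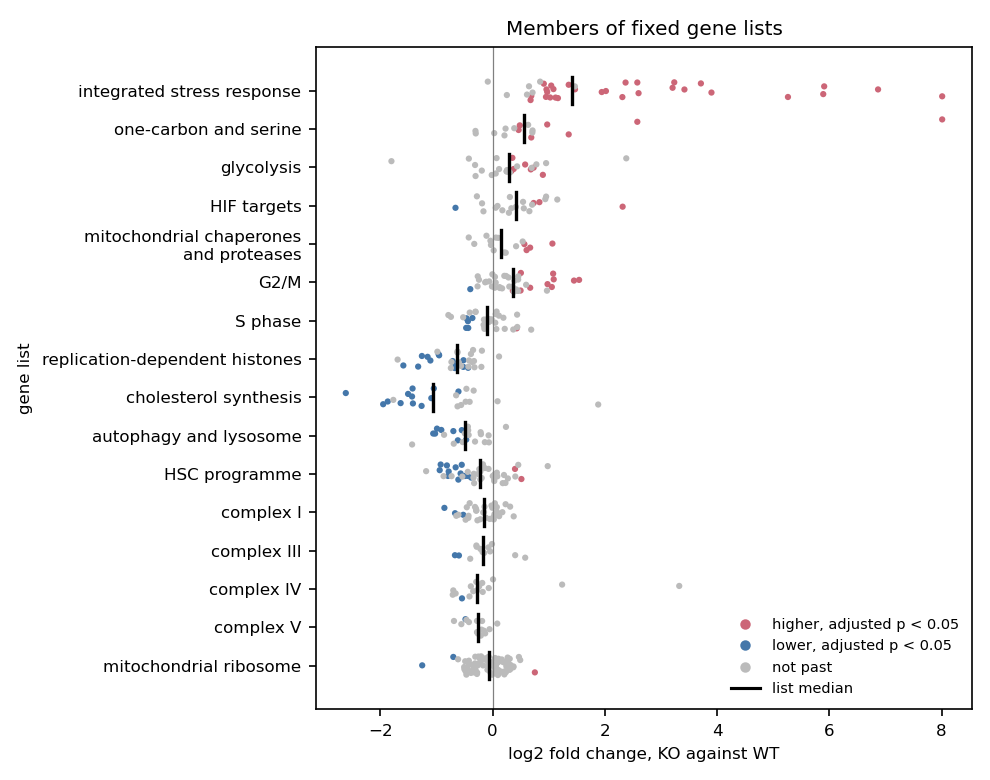
Log2 fold changes of KO against WT for each measured member of 16 fixed gene lists other than Uqcrfs1, which is not drawn, with 1 point per gene, a black line at the list median, and red (higher) or blue (lower) for genes past edgeR's adjusted p of 0.05. Of the 16 lists drawn, integrated stress response had the highest median, 1.41, and cholesterol synthesis the lowest, -1.07.

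Few nuclear genes of the respiratory chain passed the threshold. For complex I, 0 of 35 rose and 3 fell, also 3 adjusted over the list alone (median -0.15, camera adjusted p = 0.0714), and the list passed downwards without WT replicate 1 (adjusted p = 0.00373), while 0 or 1 of its genes were lower without any 1 of the other 5 libraries. Complex II had 0 of 7 past the threshold by either adjustment (median -0.11, camera adjusted p = 0.681). Without Uqcrfs1, complex III had 0 higher and 2 lower of 13, also adjusted over the list alone (median -0.18, camera adjusted p = 0.169). Both lower genes lost their calls without WT replicate 3 or KO replicate 2. Their highest adjusted p without 1 library were 0.127 and 0.178 (edgeR). The list of complex IV passed its test downwards with 1 of 16 lower, and 6 lower and 1 higher adjusted over the list alone (median -0.28, camera adjusted p = 0.0358, and adjusted p = 0.479 with an estimated correlation). Complex V also passed downwards, with 1 of 16 lower by both adjustments (median -0.26, camera adjusted p = 0.00372, and adjusted p = 0.506 with an estimated correlation). With offsets for transcript length and GC content, neither of these calls remained (adjusted p = 0.793 for complex IV and 0.224 for complex V). The complex IV call was also lost without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2, with adjusted p of 0.168, 0.0993, 0.0638 and 0.122. Without WT replicate 1, 4 genes of complex IV and 3 of complex V were lower, and without WT replicate 2, 2 genes of complex IV were higher and 0 lower. In the mitochondrial ribosome list, 1 of 77 rose and 2 fell, with 1 lower adjusted over the list alone (camera adjusted p = 0.528). Its largest change past the threshold was in Mrpl33, which fell by 1.25. The other lower gene of this list lost its call whichever library was left out (edgeR, highest adjusted p 0.131). The higher gene lost its call without WT replicate 1, WT replicate 3, KO replicate 2 or KO replicate 3 (edgeR, highest adjusted p 0.201). The TCA cycle had 1 of 22 higher, and 0 adjusted over the list alone (camera adjusted p = 0.586).

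The cholesterol synthesis list passed downwards in KO. Idi1, of isoprenoid synthesis, fell by 1.87 on the log2 scale (SE 0.25), and Insig1, the sterol-sensing regulator of the pathway, by 1.95 (SE 0.44). Of 22 genes of the list, 12 fell and 0 rose, with 13 lower adjusted over the list alone (median -1.07, camera adjusted p = 8.33e-09, and adjusted p = 0.234 with an estimated correlation). The count was 6 without WT replicate 2, 7 without KO replicate 2 and 6 without KO replicate 3.

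The antioxidant, haem and iron, and autophagy and lysosome lists also passed downwards. Fth1, the ferritin heavy chain, fell by 0.81 (SE 0.12), Gpx1, a glutathione peroxidase, by 0.80 (SE 0.10) and Prdx1, a peroxiredoxin, by 0.74 (SE 0.15). The NRF2 and antioxidant list had 6 of 21 lower and 1, Slc7a11, higher, with 9 lower and 1 higher adjusted over the list alone (median -0.39, camera adjusted p = 0.00188, and adjusted p = 0.280 with an estimated correlation). The list of haem, iron-sulfur cluster and iron genes had 7 of 27 lower and 0 higher, with 8 lower adjusted over the list alone (median -0.28, camera adjusted p = 0.00147, and adjusted p = 0.234 with an estimated correlation). The members with the smallest p were Alas2, the erythroid enzyme that starts haem synthesis, at -2.93, Fth1, and Slc25a37, the mitochondrial iron importer, at -1.19. Among autophagy and lysosome genes, 8 of 23 fell and 0 rose, with 11 lower adjusted over the list alone (median -0.49, camera adjusted p = 1.33e-05, and adjusted p = 0.236 with an estimated correlation). Map1lc3b, an LC3 gene of the autophagosome membrane, fell by 0.91. The count was 3 for the antioxidant list without KO replicate 2 or KO replicate 3, 4 for the haem list without WT replicate 1 or KO replicate 1, and 2 to 5 for the lysosome list without any 1 library other than WT replicate 2. Erythroid and macrophage genes moved with these lists. The haem and erythroid lists both hold Alas2, so their levels are partly the same values. In WT replicates 1 to 3 the mean log2 CPM was 5.49, 5.21 and 5.36 for the haem list and 4.60, 4.09 and 4.36 for the erythroid list, and 5.56, 5.37 and 5.70 for the lysosome list and 3.67, 2.49 and 5.64 for the macrophage list, and all 4 lists passed downwards in KO.

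Among the cell cycle lists, G2/M passed upwards, replication-dependent histones downwards, and S phase did not pass. In the G2/M list, 10 of 40 genes rose and 1 fell, with 17 higher and 1 lower adjusted over the list alone (median 0.36, camera adjusted p = 8.88e-08, and adjusted p = 0.234 with an estimated correlation). Cenpe, a kinetochore motor gene, rose from 116 ± 25.5 to 337 ± 28.8 CPM, Cenpf by 1.08 on the log2 scale, Smc4, a condensin subunit, by 1.06 and Kif20b by 0.98. The mitotic cyclin and kinase genes Ccnb1 and Cdk1, chosen after their values were seen, did not pass the threshold in edgeR (adjusted p = 0.994 and 0.333). Ccnb1 stood at 90.0 ± 13.3 CPM in WT and 89.7 ± 21.1 in KO. In S phase, 1 of 34 rose and 5 fell, with 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.207). Pcna, the replication clamp, fell by 0.47 (SE 0.10), and lost its call with length and GC offsets. Of 31 replication-dependent histone genes, whose transcripts accumulate in S phase, 13 fell and 0 rose, with 19 lower adjusted over the list alone (median -0.63, camera adjusted p = 2.11e-11, and adjusted p = 0.266 with an estimated correlation). Hist1h1b fell from 549 ± 77.5 to 219 ± 33.4 CPM and Hist2h2ac by 1.26 on the log2 scale, with the uncertainty that histone genes are near-identical copies. The lower count was 7 for histones without KO replicate 2, and with length and GC offsets 8 histone genes were called. For S phase the lower count was 2 without WT replicate 2 or KO replicate 2 and 1 without KO replicate 3.

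Transcript length moved with the groups beside these lists. In the decile of the tested genes with the longest transcripts, 203 genes were higher and 53 lower, and in the decile with the shortest, 21 were higher and 95 lower. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change was 0.119 with length and 0.130 with GC content. A slope on length was fitted to each library's deviations from the genes' means over the 6 libraries. In log2 per doubling, it was -0.01, -0.10 and -0.03 in WT replicates 1 to 3 and 0.03, 0.07 and 0.05 in KO replicates 1 to 3. These slopes centre on 0 by construction, so only differences between libraries can be read from them, and not their signs. The difference between the groups had an exact permutation p of 0.1 (two-sided), the smallest that 3 libraries against 3 allow. With offsets for length and GC content, 655 genes were higher and 520 lower, and 1022 of the 1391 calls were kept. The median member was 539 nt long for histones, 721 nt for complex IV, 3410 nt for G2/M and 2748 nt for the stress response list.

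**Figure D3:**
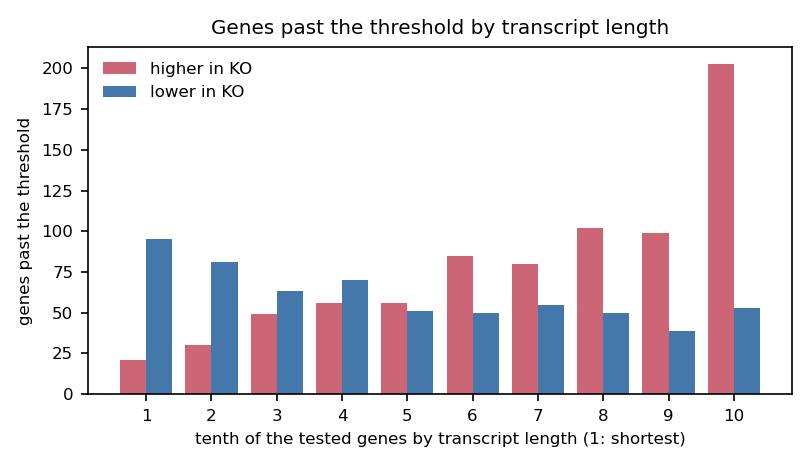
Number of genes past an adjusted p of 0.05 in KO against WT, higher in red and lower in blue, in deciles of the tested genes by transcript length from shortest to longest. Higher genes number 21 in the shortest decile and 203 in the longest, and lower genes 95 and 53.

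Genes of the stem cell programme were mixed, with more lower than higher. Of the 45 genes measured, 12 fell and 2 rose, with 13 lower and 2 higher adjusted over the list alone (median -0.22, camera adjusted p = 0.00223, and adjusted p = 0.234 with an estimated correlation). The lower count was 5 without WT replicate 1, 2 without KO replicate 2 and 3 without KO replicate 3. The list shares 5 genes with the endothelial list and 2 with the megakaryocyte list, which also passed downwards, so these calls are not independent. It also shares 3 genes with the fetal stem cell list, 2 with the mast cell, basophil and eosinophil list and 1 with the lymphoid list. Vwf, the von Willebrand factor gene expressed in a platelet-biased share of HSCs, fell by 0.79 on the log2 scale (SE 0.17). Cd34, a surface marker, fell by 0.49 (SE 0.12), with a highest adjusted p of 0.0714 without KO replicate 2. The transcription factor gene Mycn rose by 0.51 (SE 0.11). Kit, the stem cell factor receptor, stood at 751 ± 87.5 CPM in WT and 576 ± 45.3 in KO, a fall by 0.38 with a highest adjusted p of 0.122 over the fits without WT replicate 1, WT replicate 3, KO replicate 2 or KO replicate 3. Of 15 fetal stem cell genes, 0 were past the threshold by either adjustment in edgeR (camera adjusted p = 0.903). Their median was 0.03 and their mean -0.02, and 3 were higher without WT replicate 3. In the quiescence and cell cycle inhibitor list, 3 of 16 fell and 1 rose, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0714). The list passed downwards without WT replicate 2, WT replicate 3 or KO replicate 3 (adjusted p = 0.0475, 0.0169 and 0.0180) and with length and GC offsets (adjusted p = 0.0240). Txnip, a thioredoxin inhibitor gene, fell by 0.89, and the antiproliferative gene Btg1 by 1.05.

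Erythroid genes had the smallest camera p of the lineage lists. Alas2 fell by 2.93 on the log2 scale (SE 0.35). Sptb, a spectrin gene of the red cell membrane skeleton, fell by 2.45 on the log2 scale, and Epb4.2, the gene of protein 4.2, by 3.59. Slc4a1, the band 3 anion exchanger gene, fell from 174 ± 92.5 to 16.5 ± 4.18 CPM with a highest adjusted p of 0.0661 without KO replicate 2. Of 25 measured genes, 12 fell and 0 rose, with 16 lower adjusted over the list alone (median -2.08, camera adjusted p = 2.12e-15, and adjusted p = 0.156 with an estimated correlation). WT replicate 1 held the highest level of 18 of the 25 genes, and without WT replicate 1 the median was -1.66. The haemoglobin genes Hbb-bs, Hba-a2, Hbb-bt and Hbb-b1 had 0 counts in every library but had values in the RPKM table, where they were singled out after these were seen. Hbb-bs stood at 3330, 2854 and 2295 RPKM in WT replicates 1 to 3 and at 146, 215 and 93.9 in KO. Hba-a2 averaged 765 ± 129 RPKM in WT and 75.3 ± 28.7 in KO, and Hbb-bt 2121 ± 179 and 804 ± 274 (SD, n = 3 each). On the log2(RPKM + 1) scale these 3 genes fell by 4.27, 3.38 and 1.46, with limma's adjusted p of 0.00171, 0.00109 and 0.0279. Hbb-b1 did not pass (difference 0.19, limma's adjusted p = 0.985), at 131 ± 210 RPKM in WT and 94.2 ± 124 in KO. These genes have near-identical copies, and how reads with several matches were treated is not given in the sources used here.

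The macrophage, endothelial and hepatoblast lists passed downwards in KO, with uneven levels among libraries of a group. In the macrophage and monocyte list, 5 of 23 fell and 0 rose, also 5 adjusted over the list alone (median -2.57, camera adjusted p = 3.41e-08, and adjusted p = 0.294 with an estimated correlation). The chemokine receptor gene Ccr2 fell by 3.39 (SE 0.40) and the lysozyme gene Lyz2 from 168 ± 40.9 to 62.2 ± 12.5 CPM, while Csf1r, at 96.8 ± 93.5 and 9.53 ± 6.98 CPM, did not pass the threshold (adjusted p = 0.158). In the endothelial list, 4 of 21 fell and 1 rose, with 6 lower and 1 higher adjusted over the list alone (median -0.81, camera adjusted p = 0.00134, and adjusted p = 0.537 with an estimated correlation). The gene that rose was Egfl7, by 1.21. Mmrn2 fell by 3.55, and by 2.28 without WT replicate 3, with an adjusted p of 0.158. The count of lower endothelial genes was 7 without WT replicate 2 and 2, 1 and 2 without KO replicates 1, 2 and 3. WT replicate 3 held the highest level of 20 of the 23 macrophage genes and of 18 of the 21 endothelial genes. Without it the medians were -1.26 and -0.55. The scavenger receptor gene Msr1 and the protocadherin gene Pcdh17, which had the largest falls among genes without overlap and with a mean of at least 5 CPM, at -5.95 and -6.13, were also highest there and had adjusted p of up to 0.147 without it and 0.186 without it, KO replicate 2 or KO replicate 3, respectively. Their values were -3.99 and -4.29 without WT replicate 3 and -6.73 and -8.57 without KO replicate 1, and that of Pcdh17 was -5.53 without KO replicate 2. With limma-voom Mmrn2, Msr1 and Pcdh17 did not pass (adjusted p = 0.0894, 0.160 and 0.129), nor did Pcdh17 with the Y-linked level as a covariate (adjusted p = 0.133). In the hepatoblast list, 3 of 17 fell, also 3 adjusted over the list alone (median -0.60, camera adjusted p = 0.00406, and adjusted p = 0.313 with an estimated correlation). Its mean log2 CPM was 3.42, 2.76 and 3.14 in WT replicates 1 to 3 and 1.55, 1.73 and 3.18 in KO replicates 1 to 3, so that KO replicate 3 lay among the WT libraries. The call was lost without KO replicate 1 (adjusted p = 0.0549), and the median was -1.57 without KO replicate 3. The transferrin gene Trf fell by 1.44.

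The granulocyte, megakaryocyte and interferon lists passed downwards, and the mast cell, basophil and eosinophil list upwards. Among granulocyte genes, 2 of 23 fell and 1 rose, with 6 lower and 1 higher adjusted over the list alone (median -0.65, camera adjusted p = 0.00581, and adjusted p = 0.236 with an estimated correlation). The list's mean log2 CPM was 3.61, 3.71 and 2.69 in WT replicates 1 to 3 and 2.19, 2.58 and 2.75 in KO replicates 1 to 3. Without WT replicate 3, the lowest of WT, 7 genes fell and the median was -1.13, and without WT replicate 2, 4 fell. Chil3 had 84, 62 and 51 counts in WT and 0 in each KO library, at least 81.0-fold lower, and Mpo, the myeloperoxidase gene, fell by 0.62. Among megakaryocyte genes, 5 of 22 fell and 2 rose, with 6 lower and 2 higher adjusted over the list alone (median -0.47, camera adjusted p = 0.0268, and adjusted p = 0.234 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.0642), and the lower count was 1 without WT replicate 1 or KO replicate 2 and 3 without WT replicate 2, WT replicate 3 or KO replicate 3. Selp, the P-selectin gene, rose by 1.58. In the interferon response list, 4 of 31 fell by both adjustments (median -0.80, camera adjusted p = 0.000754, and adjusted p = 0.541 with an estimated correlation). WT replicate 2 held the highest level of 25 of the 31 genes, and without it the call was lost (adjusted p = 0.194), with 1 gene lower and a median of -0.40. Without WT replicate 3, 12 were lower, and without KO replicate 2, 0 in edgeR. In the mast cell, basophil and eosinophil list, 4 of 12 genes rose and 2 fell, with 5 higher and 2 lower adjusted over the list alone (median 1.76, camera adjusted p = 0.00134, and adjusted p = 0.234 with an estimated correlation). The eosinophil granule genes Prg2 and Epx rose by 2.04 and 2.93, Epx by 3.87 without WT replicate 3, and the genes that fell were Srgn and Kit, which stem cells also express. Without KO replicate 3, 2 rose, and without WT replicate 3, 1 fell. Lymphoid genes had 2 of 14 lower by both adjustments (camera adjusted p = 0.902), with a median of 0.13 above 0 and a test direction downwards. Stromal genes had 1 of 6 lower, and 3 adjusted over the list alone (camera adjusted p = 0.0921, and 0.0402 without WT replicate 3), with a median of -0.70, and of -0.29 without WT replicate 1.

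**Figure D4:**
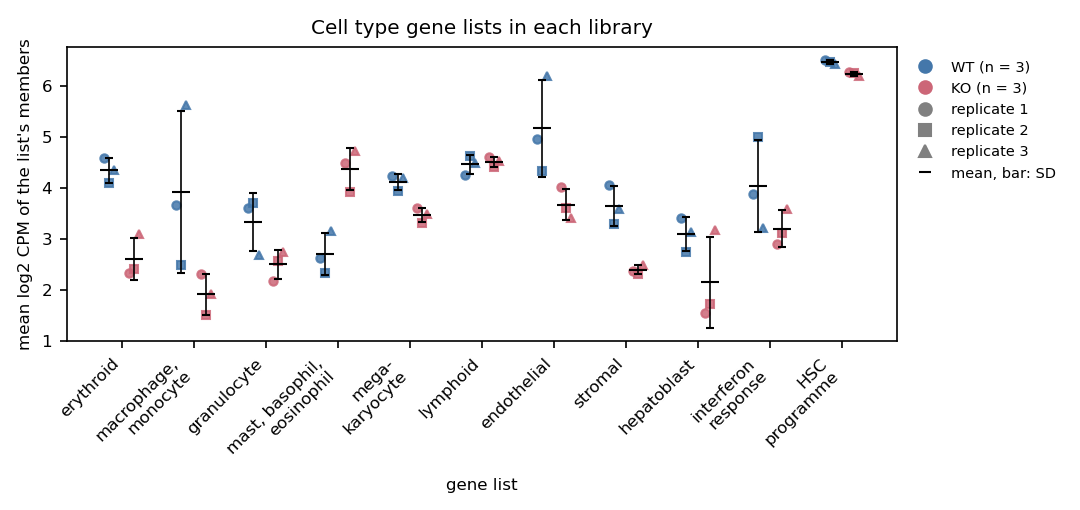
Mean log2 CPM of the members of 11 gene lists in each library. Each symbol is 1 library, horizontal marks are means and bars SDs over 3 libraries per group. The erythroid list lay between 4.09 and 4.60 in WT and between 2.34 and 3.09 in KO, and WT replicate 3 had the highest macrophage level, 5.64.

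Of the remaining lists, immediate early and cytosolic ribosomal protein genes passed downwards and chromatin enzymes upwards. Immediate early genes had 5 of 20 lower and 0 higher, with 8 lower adjusted over the list alone (median -0.53, camera adjusted p = 0.000728, and adjusted p = 0.156 with an estimated correlation). The transcription factor genes Klf6 and Klf2 fell by 1.07 and 1.14, and without KO replicate 2, 3 genes of the list were lower. Chromatin enzymes had 8 of 27 higher and 1 lower by both adjustments (median 0.21, camera adjusted p = 0.00898, and adjusted p = 0.234 with an estimated correlation). The DNA methyltransferase genes Dnmt3a, Dnmt3b and Dnmt1 rose by 0.56, 0.50 and 0.45, that of Dnmt1 not with length and GC offsets, and Idh1, a cytosolic isocitrate dehydrogenase, fell by 1.59. This list's call was lost with length and GC offsets (adjusted p = 0.125) and without WT replicate 2 (adjusted p = 0.0599), and the higher count was 4 without KO replicate 2 and 3 without KO replicate 3. Cytosolic ribosomal protein genes had 10 of 77 lower and 1 higher, with 15 lower and 1 higher adjusted over the list alone (median -0.13, camera adjusted p = 0.0219, and adjusted p = 0.778 with an estimated correlation). The call was lost without WT replicate 2 (adjusted p = 0.343) or KO replicate 2 (adjusted p = 0.251), with 0 genes lower in edgeR in both fits, and with length and GC offsets it turned upwards (adjusted p = 0.0114).

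Among p53 targets, 2 of 19 rose and 3 fell, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.632). Zmat3 rose by 1.54 and Plk2 fell by 1.42. The BCL2 family had 0 of 13 past the threshold by either adjustment in edgeR (camera adjusted p = 0.771). Endoplasmic reticulum stress genes had 2 of 15 lower, and 6 lower with 2 higher adjusted over the list alone (camera adjusted p = 0.126), and passed downwards without WT replicate 2 (adjusted p = 0.0344, 5 lower). Without KO replicate 2 the 2 lower genes lost their calls (edgeR, adjusted p = 0.0551 and 0.0630). The nucleotide and aspartate list had 4 of 24 higher and 3 lower, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.771). Its median of -0.05 and mean of 0.08 differed in sign, and 2 genes were higher without WT replicate 1 or KO replicate 2 and 1 lower without WT replicate 1, WT replicate 2 or KO replicate 3. Slc1a5, a glutamine transporter gene, rose by 0.95, and Mdh1, the cytosolic malate dehydrogenase, fell by 0.55, a call lost with length and GC offsets. The pentose phosphate list had 1 of 7 lower by both adjustments (camera adjusted p = 0.116, and fry's directional adjusted p = 0.00479). The lower gene lost its call whichever library was left out (edgeR, highest adjusted p 0.148). NF-kB genes had 2 of 11 lower by both adjustments (camera adjusted p = 0.126), and passed downwards without WT replicate 3, KO replicate 2 or KO replicate 3 (adjusted p = 0.0203, 0.0275 and 0.0127). Their median was -0.50, and -0.24 and -0.28 without WT replicate 1 and KO replicate 1. The 2 lower genes both lost their calls without WT replicate 2, KO replicate 2 or KO replicate 3. Their highest adjusted p without 1 library were 0.132 and 0.215 (edgeR). Fatty acid oxidation had 1 of 22 higher and 1 lower, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.528). Mitochondrial biogenesis and dynamics had 1 of 23 lower by both adjustments (camera adjusted p = 0.978), with a median of 0.05 and a test direction downwards.

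Libraries differed in other ways that bear on these values. Rn45s, the ribosomal RNA precursor, took 11.7, 10.5 and 11.3% of counts in WT replicates 1 to 3 and 9.92, 6.69 and 4.96% in KO replicates 1 to 3 (exact permutation p = 0.1, two-sided, the smallest possible). Xist, which is expressed from the inactive X chromosome, had 0 counts in KO replicate 2 and 5842 to 16004 in the other libraries. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 13, 836 and 1022 counts in WT replicates 1 to 3 and 0, 2358 and 604 in KO replicates 1 to 3. WT replicates 2 and 3 and KO replicate 3 therefore held both kinds of transcript. Uqcrfs1 lies on chromosome 13. Within 20 Mb of it, 28 of 179 tested genes (15.6%) were past the threshold, against 11.3% of the 11979 placed elsewhere, an odds ratio of 1.45 with a 95% interval of 0.929 to 2.19 (Fisher's exact test, two-sided, p = 0.0756). Without WT replicate 1 the ratio was 1.85 (Fisher's exact test, p = 0.00810), it was 1.14 without KO replicate 1, and it was 2.31 with limma on log2(RPKM + 0.5) without a filter, where 6 of 225 genes nearby were called (Fisher's exact test, p = 0.0530).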

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

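The tests of the length slopes, of the mast cell and eosinophil list and of WT replicate 3 were chosen after the results they bear on had been seen, and the length and GC offsets and the Y-linked covariate after seeing the data. Of the genes with 0 counts in every library and a mean of at least 0.5 RPKM, 1 passed the threshold upwards in RPKM, and it stood above all WT libraries, while 5 passed downwards, namely Hbb-bs, Hba-a2, Hbb-bt, Amd1 (log2 difference -0.66) and Zfp91Cntf (-1.86), with limma's adjusted p from 0.00109 to 0.0403. This gene, the microRNA gene Mir8114, had a mean of 109.67 RPKM in KO (19.9, 244 and 65.0 in replicates 1 to 3), against 0.0512 in WT, with limma's adjusted p of 0.0281 on the log2(RPKM + 1) scale. In the GRCm38 annotation 108 of its 111 nt overlap Glul, the glutamine synthetase gene, whose counts fell by 0.84 on the log2 scale in KO (edgeR, adjusted p = 0.00019). RPKM of other microRNA genes with 0 counts jumped between libraries of 1 group. Examples chosen after their values were seen are Mir135a-1, at 0, 0 and 1913 in WT replicates 1 to 3, and Mir1306, at 0, 789 and 0 in KO replicates 1 to 3. Whether the Mir8114 values reflect a transcript of that gene was not tested.

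The number of genes past the threshold was set against regrouping of the libraries and against their sex make-up. Only 10 splits of the 6 libraries exist, too few for a share under 0.05, and 1 of them, the real one, reached the real value both for genes and for lists. The real split gave 1391 genes and the highest of the other splits 0, and for gene lists the real split gave 25 and the others 9 to 14. The other splits keep WT and KO libraries on both sides in unequal number. The group difference then adds to the spread within the sides and stays in part between them. Their counts therefore give no rate of false calls. With the Y-linked level as a covariate, 100% of the 1391 genes kept their direction and an unadjusted p under 0.05 in edgeR, and 1343 kept an adjusted p under 0.05. Y-linked counts overlapped between the groups, at 13 to 1022 in WT and 0 to 2358 in KO. Sex make-up by this measure thus did not follow the groups. The covariate could therefore remove little, and the kept calls by themselves decide little. Differences between embryos or days that follow the genotype stay open, as the labels name none. The deposited column headers carry a code with the letter A for every WT library and B for every KO library. Its meaning is not given, and it divides the libraries as the genotype does.

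The trend of long transcripts rising in KO may reflect RNA quality or library chemistry, or it may be part of the response to the knockout. After offsets for length and GC content, the median of the integrated stress response list was 1.31 (1.41 before) and that of the G2/M list 0.39 (0.36 before), with adjusted p of 1.23e-74 and 5.25e-10, so the trend is not the whole source of either. The histone list went from -0.63 to -0.38 (SE 0.07), still past its threshold (adjusted p = 1.62e-06) but within its SE of 0.5 of its first value, so a part set by the trend cannot be told apart. As to the trend itself, the groups' mean slopes differed by 0.10 (SE 0.03) with no overlap, and a handling difference that follows the groups cannot be told apart from genotype. The lower Rn45s share in KO runs along the same division and stays equally open.

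Lower erythroid, macrophage and endothelial transcripts may come from fewer cells of those types in the KO samples or from lower expression in the HSCs. A lower share of every other cell type would also lower mast cell and eosinophil genes, but their list, of which stem cells also express Kit, Gata2 and Srgn, passed upwards with a median of 1.76 (SE 0.58, adjusted p = 0.00134, and adjusted p = 0.234 with an estimated correlation), and a change in those cells themselves stays open. Without WT replicate 3 the macrophage median stayed at -1.26 (SE 0.22) and the erythroid median at -1.76 (SE 0.38). These SEs resample genes and not libraries. The macrophage list's mean log2 CPM was 3.67 and 2.49 in WT replicates 1 and 2, against 2.32, 1.51 and 1.92 in KO. The erythroid list's mean log2 CPM was 4.60 and 4.09 in WT replicates 1 and 2, against 2.34, 2.41 and 3.09 in KO. WT replicate 3 thus does not alone account for the erythroid fall. In the macrophage list WT replicate 2 lay close to KO replicate 1. That list's call over all libraries was lost with an estimated correlation (camera, adjusted p = 0.294). How far the macrophage fall goes beyond WT replicate 3 stays open. Among the 25 erythroid genes WT replicate 3 was highest in 2 and WT replicate 1 in 18, with a median of -1.66 without WT replicate 1. For the endothelial list the median without WT replicate 3 was -0.55 (SE 0.54, camera adjusted p = 0.00614). Its mean log2 CPM was 4.97 and 4.34 in WT replicates 1 and 2, against 4.01, 3.61 and 3.42 in KO. A contribution of WT replicate 3 alone cannot be told apart in this list from a group difference. Of the 2 most abundant members of each list, Slc4a1, Car2 (349 ± 69.9 CPM in WT and 167 ± 33.4 in KO) and Lyz2 passed the threshold, Csf1r (96.8 ± 93.5 and 9.53 ± 6.98), Eng (186 ± 16.3 and 167 ± 14.2) and Tie1 did not, and any sort or gate is not given in the sources used here.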

How the results depend on the processing

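The length and GC offsets, alone and with the replicate block, the covariate for the Y-linked level and the one-carbon list without its stress response members were chosen after seeing the data, and all other alternatives before. Of the 1391 genes called, 0 were called in the opposite direction under any alternative run. Without 1 library in turn the number of genes ranged from 712 to 1263, with 448 to 717 higher and 264 to 546 lower. The total moved by more than 1.5 times without KO replicate 2 or KO replicate 3 (833), and the lower genes also without WT replicate 1 (383). With limma on log2(RPKM + pseudocount) the total was 503 (318 higher, 185 lower) for a pseudocount of 1, 492 (316 and 176) for 0.1, 505 (319 and 186) for 0.5, and 194 (132 and 62) for 0.5 without a filter. A minimum log2 fold change of 1 left 465 (217 and 248), and an adjusted p of 0.1 gave 947 lower genes. With the replicate number as a block there were 762 higher and 579 lower genes, and 1239 calls were kept, while the calls of Chac1 and Slc4a1 were lost (adjusted p = 0.102 and 0.0527), also with the offsets added (0.0965 and 0.0795), as then was that of Cd34 (0.0555). Libraries with the same number correlated at 0.0224, 0.0117 and -0.00343 in their deviations from the group means, so the numbers were not taken as pairs, and WT replicate 2 correlated better with KO replicate 3, at 0.0129, than with its own number. DESeq2 on its default settings, without the main filter on low counts, called 934 higher and 867 lower genes, against 937 and 841 for edgeR without that filter, limma-voom 728 and 557, upper-quartile scaling 739 and 666, and the offsets 655 and 520.

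With an estimated correlation 1 list passed, and 41 passed by fry's mixed p, which asks only whether members change in either direction. By fry's directional p 18 passed, and the calls of complexes IV and V and of the granulocyte, macrophage, hepatoblast, endothelial, interferon, cytosolic ribosome and histone lists were lost (adjusted p from 0.0595 to 0.286), while pentose phosphate (0.00479) and stromal genes (0.0291) passed. The integrated stress response list passed under all 18 list settings. With the length and GC offsets, and with the block added, the direction of the test reversed for complex I (adjusted p = 0.703 and 0.712), complex III (0.849 and 0.859), complex IV (0.793 and 0.828), the mitochondrial ribosome (0.455 and 0.447), the cytosolic ribosome (0.0114 and 0.0231), fetal stem cell genes (0.793 and 0.828) and mitochondrial biogenesis (0.936 and 0.926). Mitochondrial biogenesis also reversed with the block alone (0.985), by fry (0.966) and without WT replicate 1 or KO replicate 3 (0.819 and 0.835, highest without 1 library 0.924). Fetal stem cell genes reversed without mitochondrial, haemoglobin and short non-coding RNA genes and Rn45s (0.975). They also reversed without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 (0.987, 0.512, 0.869 and 0.848, lowest without 1 library 0.221). Lymphoid genes reversed without KO replicate 2 (0.869, range without 1 library 0.741 to 0.920) and the nucleotide list without WT replicate 3 (0.908, lowest 0.621). Of these only the cytosolic ribosome was past the threshold in the other direction, and the cause was not tested.

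Among named genes, reversals were in genes not past the threshold, except Rpl39, which went from a log2 fold change of -0.35 to 0.11 with the offsets, with or without the block, and lost its call without WT replicate 2 or KO replicate 2 (highest adjusted p 0.132). Tie1 reached 0.071 without WT replicate 3 and lay as low as -0.18 without WT replicate 1. Xist and the Y-linked genes changed sign with the libraries kept: Xist to 0.27 and 0.40 without WT replicate 1 and KO replicate 2, Ddx3y to -0.07 and -0.81 and Kdm5d to -0.47 and -1.53 in the same fits, Eif2s3y to -0.28 without KO replicate 2, and Uty to 0.11, 0.44, 0.49 and 0.20 without WT replicate 2, WT replicate 3, KO replicate 1 and KO replicate 3. The other ends of these ranges were -0.80 for Xist, 1.09 for Ddx3y, 0.70 for Kdm5d, 2.45 for Eif2s3y and -1.97 for Uty. With limma-voom Ddx3y was at -0.27 and Kdm5d at -0.56, and Kdm5d was at -0.12 with sample weights, -0.16 with the block, -0.25 with block and offsets, -0.31 with the Y-linked covariate, and -0.056, -0.10 and -0.076 with RPKM pseudocounts of 1, 0.1 and 0.5, the last also -0.076 without a filter. The cause was not tested.

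The odds ratio near Uqcrfs1 stayed above 1 in all fits and passed an unadjusted 0.05 with upper-quartile scaling (1.56), DESeq2 (1.61), limma-voom (1.66, and 1.82 with sample weights), no filter (1.63), non-robust shrinkage (1.65) and an adjusted p of 0.1 for calls (1.48). It ranged from 1.14 to 1.85 over the fits without 1 library, and was 2.31 with limma on log2(RPKM + 0.5) without a filter (p = 0.0530), the highest of all fits, 1.32 with the block (p = 0.227), 1.18 with the offsets (p = 0.445) and 1.05, the lowest, with both (p = 0.803, all Fisher's exact test), and the cause was not tested. What depth limits was not tested apart from the number of libraries.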

Other observations

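The gene groups and tests here were chosen after the data had been seen. Their p-values are unadjusted and come from the same values, so they give no independent support. A list of MHC class II and dendritic cell genes, which present antigen, fell in KO beside the macrophage and monocyte list. Cd74, the invariant chain, fell by 2.41 on the log2 scale (SE 0.38), H2-Aa by 2.58 and H2-Ab1 by 2.07, and 7 of the 10 genes of the list fell, with 0 higher. The list's median was -2.24 (camera p = 1.94e-07, and p = 0.0307 with an estimated correlation). The macrophage and monocyte list had a median of -2.57 (camera adjusted p = 3.41e-08, and adjusted p = 0.294 with an estimated correlation). In WT replicates 1 to 3 the mean log2 CPM was 3.84, 3.47 and 2.90 for the MHC class II list and 3.67, 2.49 and 5.64 for the macrophage list, and in KO replicates 1 to 3 it was 1.10, 1.19 and 1.76, and 2.32, 1.51 and 1.92. The count of lower MHC class II genes was 3 without WT replicate 1 and 4 without KO replicate 3. H2-Aa had an adjusted p of up to 0.124 without WT replicate 2 or KO replicate 3, and H2-Ab1 one of 0.132 without WT replicate 1, and neither passed with limma-voom.

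Transporters of neutral and cationic amino acids were partly higher. Slc1a4 rose by 2.41 (SE 0.25), Slc6a9, a glycine transporter, by 1.89 (SE 0.39, with a highest adjusted p of 0.0609 without KO replicate 2) and Slc7a1 by 1.06 (SE 0.12). Of 13 transporters outside the stress response list, 4 rose and 0 fell, with a median of 0.04 (camera p = 0.00320, and p = 0.106 with an estimated correlation). Reads assigned to Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 3.14 ± 0.267% of counts in WT and 2.06 ± 0.319% in KO (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest possible). Iars2, the most abundant of the other mitochondrial synthetase genes measured, stood at only 88.8 ± 12.5 CPM in WT. Whether the Lars2 counts reflect its mRNA is therefore open, and the Rn45s share fell along the same division.

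Cytosolic aminoacyl-tRNA synthetase genes outside the stress response list were noticed among the higher genes. Of 15, 7 rose and 0 fell, including Cars by 1.87 (SE 0.17), Aars by 1.36 (SE 0.13) and Yars by 1.26 (SE 0.15), and of 16 mitochondrial ones 1 rose, Aars2 by 0.88 (SE 0.28, with 0 past the threshold and an adjusted p of up to 0.203 without WT replicate 1, WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3), with Lars2 left out for its very high counts. The cytosolic list had a camera p of 1.67e-14 (p = 0.00972 with an estimated correlation) and the mitochondrial list one of 0.0855 (p = 0.189). The hypothesis that the cytosolic but not the mitochondrial enzymes may rise was tested by the difference of their median log2 fold changes, 0.34 and 0.25. The difference was 0.0929, with a permutation p of 0.522 (two-sided, 100000 resamples across genes, which are not independent replicates). With 7 of 15 past the threshold, the median falls on a member that did not pass, and a p that misses the threshold does not exclude a difference. The cytosolic set also leaves out any enzyme of the stress response list, of which 29 of 36 genes rose. The comparison thus does not cover the cytosolic enzymes as a whole, and the hypothesis stays open.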
